A study of Homo sapiens with 6 samples.

How the data were processed

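The series holds 6 libraries of nascent RNA from human bronchial epithelial cells, labelled by the time of release from a block of transcription. Per the labels' protocols, cells were held in 100 uM DRB, an inhibitor that keeps RNA polymerase II from entering elongation, for 3 hours. They were then washed and released into 500 uM 4-thiouridine, which marks the RNA made from then on. Actinomycin D at 5 ug/ml stopped elongation, and splicing could go on for a further 20 min. Nuclear RNA was taken, the labelled RNA was purified, ribosomal RNA was depleted, and Illumina libraries were made. The labels give 1 library at 5 min (replicate B), 2 at 10 min (A and B), 2 at 20 min (A and B) and 1 at 40 min (A). The treatment text itself names 10, 20 and 40 min only.

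The authors deposited 4 tables, and their values are counts, per the file headers the number of unique reads crossing a feature. The tables are named intron, join3, join5 and nested. Features of the first are called known introns here, and known means listed there, since no annotation was checked. Each row gives a chromosome, a start, an end, a strand and 1 whole-number count. The deposited intron table carries its count column a second time, with equal values. No column names a library, a time or a replicate, and the files do not say whether a count is a sum over libraries or comes from 1 of them. Rows of the intron, join5 and nested tables are sorted by chromosome and position in 6 successive runs, as many as there are libraries, and no feature is listed more than once. The first run holds 44860 known introns (97.0%), 1364 join5 events (51.3%) and 248 nested events (54.9%). What a run stands for is not stated, so runs were not used as samples. If a run stood for a library, shares and ratios between features of different runs would compare counts of different libraries. The join3 table is sorted by length and shows no runs. The smallest count in each table is 4, so lower features are not listed. Alignment with STAR and the builds hg19 and hg38 are named in the submitters' processing notes. Versions, the counting rule and the filters are not given in the sources used here.

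The main processing limit follows from this layout. The tests planned before the data were examined (slopes over release time, 20 min against 10 min, class shares by library, gene lists) need 1 value per library and were not run. No p-value is given, since features are not replicates. What was computed are totals, shares, lengths and positions over the 4 tables as deposited. Shares carry Wilson intervals at 95% confidence, medians carry order-statistic intervals, and rates per length carry exact Poisson intervals. All of these cover counting error only: reads copied by PCR are not independent molecules, and the spread between libraries cannot be seen. The depth of each library is likewise unknown.

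Coordinates were read as hg19. In 13 of the chromosomes some features, 1160 in all, end past the last gene of a GRCh38 gene table, and hg19 is the other build that the notes name. The length column of the join3 table equals end minus start in every row, so positions were read as half-open and are printed with 1 added to the start. A genome and annotation of hg19 were not used here, and the files do not pair positions with genes, so features are named by position and the fixed gene lists were not tested. No sequence was examined.

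What each table holds was tested from the coordinates. Features on 1 strand were matched to listed introns on the same strand by an identical 5′ or 3′ splice site. Features listed on both strands, 843 in all, were left out of the matching. An event shorter than the intron it shared a site with was called inside that intron, and where several introns qualified the one with the most reads was used. The share of an event in its own intron is its reads out of its reads plus those of the intron. The planned minimum for the pooled share was 20 event reads. A gap above 0 and under 300 nt between the inner sites of a join5 and a join3 event of the same intron was called exon-sized; the limit of 300 nt and this comparison were chosen after the data were seen. Random placement reassigned the join3 sites among the paired introns, as a fraction of intron length, 1000 times. Length lists matched on reads were drawn 10000 times. The matching was tested on simulated data: known events were placed among 600 listed introns, and 150 of 150 exon-sized pairs were recovered. These introns were all over 1 kb and shared no 5′ or 3′ site with each other. The choice among several qualifying introns was therefore not tested.

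Features were named by a rule fixed before the data were examined: the 10 with the most reads in each table, and the 10 events with the highest share of their own intron among events with 100 or more reads. Parts of the rule that need a test over time named no feature. Segments between paired events, the window of chromosome 19 and neighbouring introns were chosen after their values were seen. Alternatives were other read minimums, other denominators, leaving out the 10 features with the most reads, leaving out both-strand features, other gap limits, leaving out 1 window and keeping the first run of rows only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.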

Results

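Splice junctions of newly made RNA were counted in human bronchial epithelial cells, the cells that line the larger airways, after transcription had been blocked and released for 5 min (1 library), 10 min (2), 20 min (2) or 40 min (1). The series' title names recursive splicing, the removal of an intron in more than 1 step, as a subject of the study. The tables used here list 51724 features with 2436705 unique reads in 4 classes: known introns, and the 3 classes of other junctions named join3, join5 and nested. Known means listed as an intron, and whether the other sites are annotated was not examined. Each feature has 1 read number, and whether it is a sum over libraries or comes from 1 of them is not stated, so counts set side by side may come from different libraries. There is therefore no replicate error, and no value is given by release time. Positions are on hg19, as read from the tables, and features are named by position.

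Nearly all reads crossed known introns. The 46256 known introns held 97.6% of the reads (interval 97.6 to 97.6%). The 2657 join5 events held 1.22% (1.21 to 1.23%), the 2359 join3 events 1.03% (1.02 to 1.05%) and the 452 nested events 0.136% (0.131 to 0.141%). Join3 events had 0.847 reads per join5 read (0.833 to 0.862), and nested events had 0.111 (0.107 to 0.115). The typical event was shallow: the median was 6 reads for join3, 5 for join5 and 5 for nested events, against 16 for known introns. The lowest listed value of 4 reads was held by 31.2% of join3, 32.4% of join5 and 38.7% of nested events, but by 7.64% of known introns. When only features with at least 10 reads were counted, join3 events held 0.674% of reads, join5 events 0.812% and nested events 0.0582%.

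The class shares rested in part on a few loci. The 10 events with the most reads held 21.7% of join5 reads, 14.0% of join3 reads and 12.6% of nested reads, while the 10 introns with the most reads held 1.93% of intron reads. Without those 10 features per table, the join3 reads per join5 read came to 0.931.

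The listed introns were short. Their median length was 429 nt (interval 423 to 436 nt), and weighted by reads it was 332 nt. Introns under 1 kb made up 74.0% of the list, introns of 1 to 10 kb 25.5% and introns of 10 to 100 kb 0.504%. The longest was 60941 nt, and 0 listed introns reached 100 kb. Shorter introns carried slightly more reads: the medians were 18, 13 and 10 reads in these 3 length classes, and Spearman's rho between length and reads across introns was -0.12 (introns are not independent replicates). Join3 and join5 junctions spanned more than the known introns at the median, 589 nt (558 to 629 nt) and 570 nt (539 to 596 nt). Nested junctions had a median of 399 nt (348 to 471 nt), whose interval overlaps that of known introns.

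**Figure D1:**
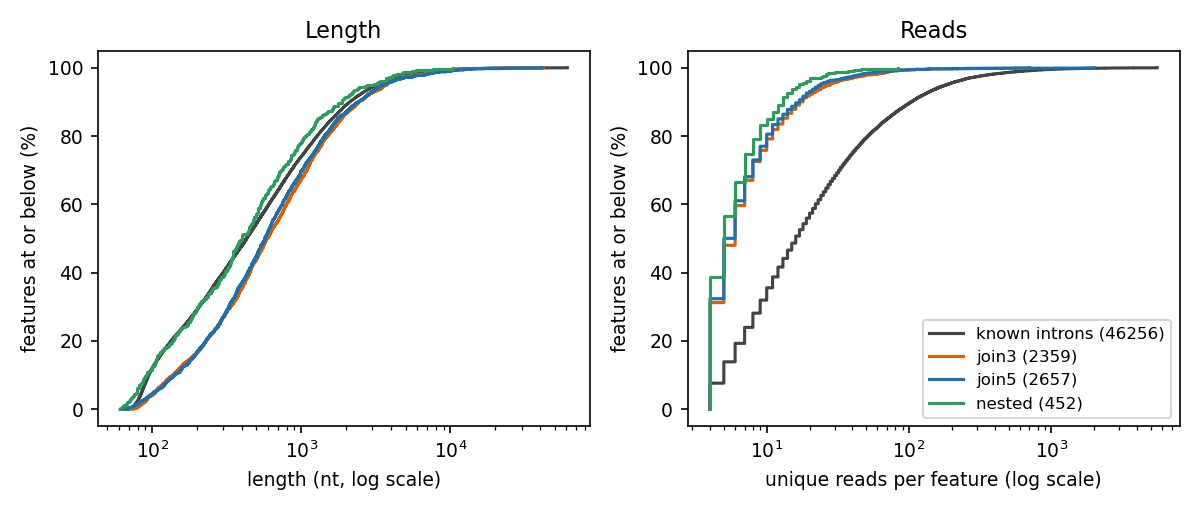
Cumulative share of features (%) by length in nt (left, log axis) and by unique reads per feature (right, log axis), with 1 line per class and the number of features in the legend. Join3 and join5 junctions lie to the right of known introns in length, with medians of 589 and 570 nt against 429 nt, and all 3 event classes lie to the left in reads.

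The known introns with the most reads lay on chromosomes 3, 11, 12 and 17. The first was an intron of 228 nt on chromosome 3, from 186504063 to 186504290 on the plus strand, with 5552 reads. The second, of 336 nt, lay on chromosome 11 from 62622024 to 62622359 on the minus strand and had 5228 reads. The other 8 of the 10 had 3788 to 4837 reads and were 89 to 358 nt long.

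Where an event shared a splice site with a known intron, which site it was set join5 and join3 events apart. Of 2611 join5 events on 1 strand, 1362 (52.2%, interval 50.2 to 54.1%) used the 5′ splice site of a listed intron, and 20 used a listed 3′ splice site. Of 2328 join3 events, 1369 (58.8%, 56.8 to 60.8%) used the 3′ splice site of a listed intron, and 26 used a listed 5′ site. Thus 1321 join5 events ran from a known 5′ site to a 3′ site inside the intron, and 1342 join3 events ran from a 5′ site inside the intron to its known 3′ site. Another 41 join5 and 27 join3 events only reached past the end of the intron. The join5 and join3 events that used no listed site are not placed by these coordinates. Only join events inside a listed intron enter the shares, the distances and the pairs of join5 with join3 events below. Of 441 nested events, 21 shared a boundary with a listed intron of their strand, and 109 (24.7%, 20.9 to 28.9%) lay inside one. These 109 include 29 events inside a single intron of chromosome 19, in the crowded window described below.

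Join events fell inside 2142 of 45501 listed introns on 1 strand (4.71%, interval 4.52 to 4.91%). Of these, 1211 held a join5 event, 1218 a join3 event and 287 both. Introns with an event were longer than the others, with a median of 1070.5 nt (1021 to 1131 nt) against 410.0 nt (403 to 416 nt). They also had more reads, 32 against 16 at the median. Where an event lay inside several listed introns, only the one with the most reads was counted as holding it. That rule by itself favours introns with more reads, here and in the shares by read class below. Among 10000 lists of other introns matched on reads, the median length was at most 426 nt. The share of introns with an event rose with length and with reads. Below 1 kb it was 1.69% for introns with 4 to 19 reads and 7.25% (6.47 to 8.11%) for introns with 100 or more. From 1 to 10 kb the same 2 values were 5.96% and 23.8% (21.1 to 26.6%). Of introns from 10 to 100 kb with 20 to 99 reads, 23 of 44 held an event (52.3%, 37.9 to 66.2%). Only 12 introns of that length had 100 or more reads, and 3 of these held one. Of all introns with 100 or more reads 10.5% held an event.

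**Figure D2:**
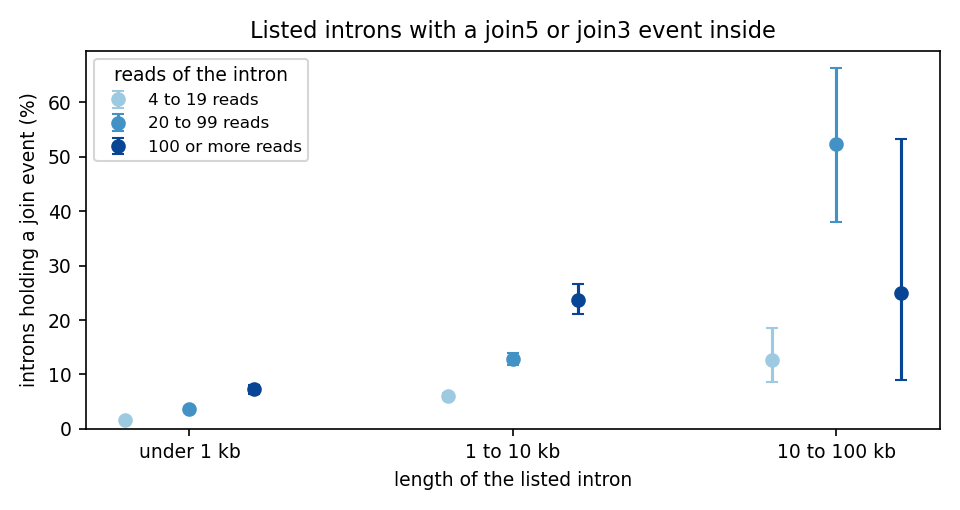
Percent of listed introns that hold a join5 or join3 event, by intron length class, with 1 point per read class of the intron and bars for the 95% Wilson interval. In the first 2 length classes the share rises with reads, from 1.69 to 7.25% below 1 kb and from 5.96 to 23.8% at 1 to 10 kb; the last point rests on 12 introns.

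Where its intron was listed, which takes at least 4 reads, an event inside it usually took the smaller part of the reads. Events whose intron fell under that minimum have no share here, which can leave out high shares. Where an event lay inside several listed introns, the one with the most reads was used, which gives the lowest of its possible shares. The median share of an inside event was 17.9% for join5 (interval 16.9 to 19.2%) and 16.7% for join3 (15.4 to 17.9%). The event outnumbered the intron in 133 join5 events (10.1%, 8.56 to 11.8%) and 132 join3 events (9.84%, 8.36 to 11.5%). These shares were lower in introns with more reads, and no event under 4 reads is listed. For introns with 4 to 19 reads the median was 38.5% for join5 and 40.0% for join3, and for introns with 100 or more reads it was 2.95% and 3.35%. Among events with at least 20 reads the pooled share was 34.5% (34.0 to 35.1%) over 112 join5 events and 25.8% (25.3 to 26.2%) over 139 join3 events. Over all inside events the pooled shares were 12.1% and 10.7%. The higher values rested on few loci: without the 10 events with the most reads of each class they were 18.9% and 17.4%. The rows of the intron and join5 tables run over the chromosomes 6 times, and 704 of the 1321 inside join5 events (53.3%) stood in another run than their intron. For the 616 events in the first run together with their intron, the median share was 17.0%, inside the interval over all inside events, and the pooled share with at least 20 reads was 34.1%. Join3 events are sorted by length and could not be compared in this way. Event reads followed intron reads weakly across events, with Spearman's rho of 0.10 for join5 and 0.16 for join3.

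The inside events with the highest shares were taken from those with 100 or more reads, a minimum that itself favours high shares. The highest share among the 24 inside events with 100 or more reads belonged to a join5 event on chromosome 3, from 186505672 to 186506098 on the plus strand. It had 2005 reads against 63 for its intron, which ends at 186506913, a share of 97.0% (96.1 to 97.6%). The join3 event of the same intron, from 186506210 to 186506913, had 566 reads and a share of 90.0% (87.4 to 92.1%). A second intron of chromosome 3, from 156870946 to 156876654 on the minus strand, had 111 reads of its own. Its join5 event, from 156874873 to 156876654, had 1789 reads (94.2%, 93.0 to 95.1%), and its join3 event, from 156870946 to 156874799, had 708 (86.4%, 83.9 to 88.6%). The 10 highest shares ran from 78.7 to 97.0% and also included join3 events on chromosomes 1 and 17 and a further one on chromosome 3, at 87.2%, 87.3% and 86.1%. The remaining 3 were join5 events on chromosomes 2, 20 and 22, at 81.7%, 83.5% and 78.7%.

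Many internal sites lay close to the known one. The internal 3′ site of a join5 event was under 100 nt upstream of the known 3′ site in 398 events (30.1%), and the internal 5′ site of a join3 event was under 100 nt downstream of the known 5′ site in 279 (20.8%). Single distances stood out. The most frequent distance up to 30 nt was 3 nt for join5 events, with 26 events against a mean of 4.34 at the other distances and a next highest of 14 at 16 nt. For join3 events it was 4 nt, with 35 events against a mean of 4.38 and a next highest of 13 at 5 nt. The peaks held 1.97% of inside join5 events and 2.61% of inside join3 events, and 3.48% and 1.33% of those with at least 10 reads. The last 2 values rest on a part of the 26 and 35 events, and no interval was computed for them. Tandem 3′ splice sites 3 nt apart and tandem 5′ splice sites 4 nt apart are known forms of alternative splicing. No join5 event lay 7 to 10 nt from the known 3′ site, where 14 join3 events lay at those distances from the known 5′ site; 112 join5 and 91 join3 events lay at 11 to 30 nt. Distances that are multiples of 3, which keep the reading frame, made up 32.4% of join5 distances under 100 nt (28.0 to 37.2%) and 22.9% of join3 distances (18.4 to 28.2%). Both percents include the peaks: 26 join5 events at 3 nt, a multiple of 3, and 35 join3 events at 4 nt, which is not.

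**Figure D3:**
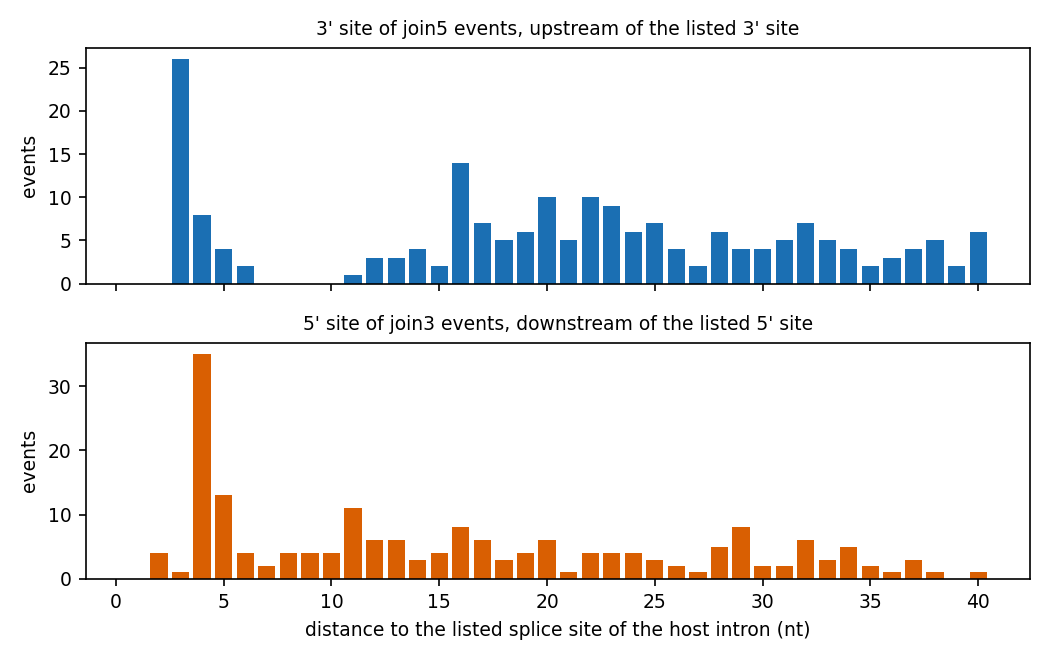
Number of inside join5 events by the distance in nt of their 3′ site from the known 3′ site (top), and of inside join3 events by the distance of their 5′ site from the known 5′ site (bottom), from 1 to 40 nt. Join5 events peak at 3 nt (26 events) with none at 7 to 10 nt, and join3 events peak at 4 nt (35 events).

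Where an intron held both kinds of event, their internal sites were usually an exon length apart. The 287 introns with both gave 382 pairs, and in 268 pairs (70.2%, interval 65.4 to 74.5%) the 5′ site of the join3 event lay downstream of the 3′ site of the join5 event by less than 300 nt. These pairs fell in 235 introns and had a median gap of 111 nt (100 to 117 nt). With at least 10 reads on both events, 78 introns had such a pair. The gap between 21457 neighbouring pairs of known introns under the same limit had a median of 120 nt. Random placement of the sites gave a median of 79 such pairs and at most 104. In 0 pairs did the 2 sites coincide, in 52 the join3 site lay upstream of the join5 site, and in 62 the gap was 300 nt or more. The exon-sized pairs took in 252 join5 events (19.1% of those inside a listed intron, 17.0 to 21.3%) and 250 join3 events (18.6%, 16.6 to 20.8%).

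The reads on both junctions of an exon-sized pair were mostly near each other where reads were few and less often so where they were many. The median log2 ratio of join5 over join3 reads was -0.06 (interval -0.26 to 0.00), with join5 higher in 110 pairs, join3 higher in 136 and 22 equal. Reads were within 2-fold in 187 of 268 pairs (69.8%), and in at most 56.7% when the partners were reshuffled 1000 times. The reshuffling did not hold the read level of the locus. It therefore cannot tell balance across a segment from a read level that both junctions share. Most of the pairs within 2-fold, 120 of 187, had under 20 reads on both junctions together, where the listing minimum of 4 leaves little room to differ. Of all 140 pairs with under 20 reads together, 85.7% were within 2-fold, against 84.0% of neighbouring known introns with as many. A pair sets 1 join5 event against 1 join3 event, so reads split over several events on 1 side can make it uneven. Pairs of 1 intron can share an event, so values are also given for the pair with the most reads of each intron. With 20 or more reads together, 52.3% of 128 pairs were within 2-fold (43.7 to 60.8%), and 59.1% of 110 with 1 pair per intron (49.7 to 67.8%). Neighbouring known introns with as many reads gave 69.1%. The shortfall lay mainly at higher reads. With 20 to 49 reads, 62.7% of 75 pairs were within 2-fold (51.4 to 72.7%), against 68.9% of neighbouring introns. With 50 to 99 reads, 43.5% of 23 pairs were (25.6 to 63.2%), against 68.7%. With 100 or more reads, 33.3% of 30 pairs were (19.2 to 51.2%), and 43.5% of 23 with 1 pair per intron (25.6 to 63.2%), against 69.6%. Among the 10 introns with the most reads on such a pair, 3 were within 2-fold, and the log2 ratios ran from -6.35 to 1.85. Among the more even pairs, the intron on chromosome 10 from 112058549 to 112063225, with 72 reads, had 138 join5 and 134 join3 reads around a segment of 190 nt from 112060305 to 112060494. The 2 introns of chromosome 3 named above were less even, with, for the join3 event of most reads in each, 2005 against 566 reads around 111 nt (186506099 to 186506209) and 1789 against 708 reads around 73 nt (156874800 to 156874872). On chromosome 2 the intron from 38975796 to 38976670, with 239 reads, had 1067 join5 and 399 join3 reads around 107 nt (38976382 to 38976488), and a second join3 event of 563 reads that began further from that segment. The length of the segment was a multiple of 3 in 34.0% of pairs (28.5 to 39.8%) and in 38.9% of the gaps between known introns (38.3 to 39.6%), a difference within counting error.

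**Figure D4:**
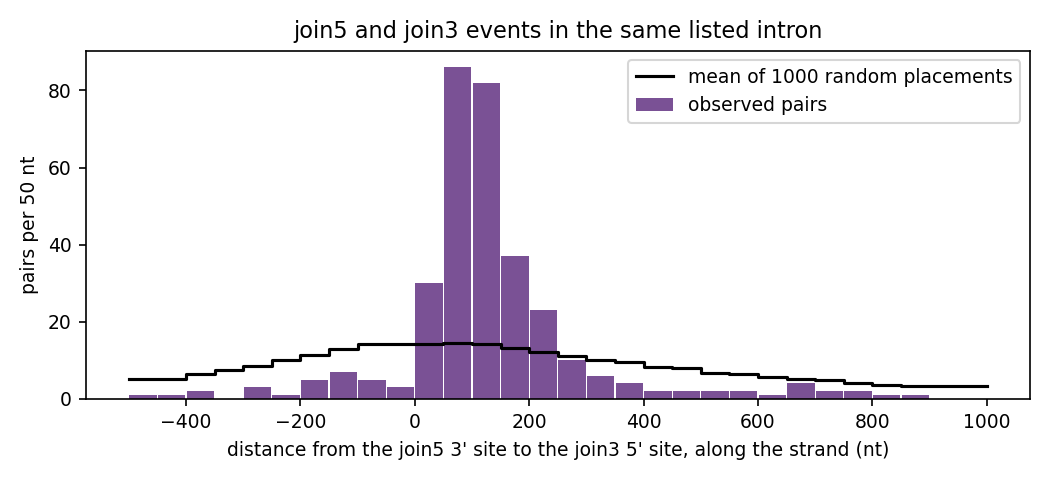
Number of pairs per 50 nt by the distance in nt from the 3′ site of the join5 event to the 5′ site of the join3 event in the same intron (bars), and the mean of 1000 random placements (line). Of 382 pairs, 268 lie above 0 and under 300 nt, against at most 104 at random.

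Nested events were few and unevenly spread. The one with the most reads spanned 548 nt on chromosome 3, from 156398345 to 156398892 on the plus strand, with 84 reads, and the other 9 of the 10 had 26 to 64 reads. Of the 441 nested events on 1 strand, 35 shared their 5′ site with a join3 event and 42 shared their 3′ site with a join5 event. A join5 event ended less than 300 nt upstream of 29 of them, a join3 event began less than 300 nt downstream of 33, and 7 had both. Chromosome 19 held 54 nested events (11.9%, interval 9.27 to 15.3%) but 6.19% of known introns (5.98 to 6.41%). Of these, 29 lay in 1 window of 2233 nt, from 34881465 to 34883697 on the plus strand, inside a listed intron of 11728 nt with 18 reads. In that window 27 of 29 events (93.1%, 78.0 to 98.1%) had a length within 2 nt of a multiple of 50, against 39 of the 423 elsewhere (9.22%, 6.82 to 12.4%), where even spread gives 10%. The unit of 50 nt was chosen from the lengths in the window, and the same 27 events are also within 2 nt of a multiple of 25, where even spread gives 20%. Without the window, chromosome 19 held 5.91% of nested events (4.03 to 8.58%). Among nested events with at least 10 reads, the window included, it held 21.1%.

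**Figure D5:**
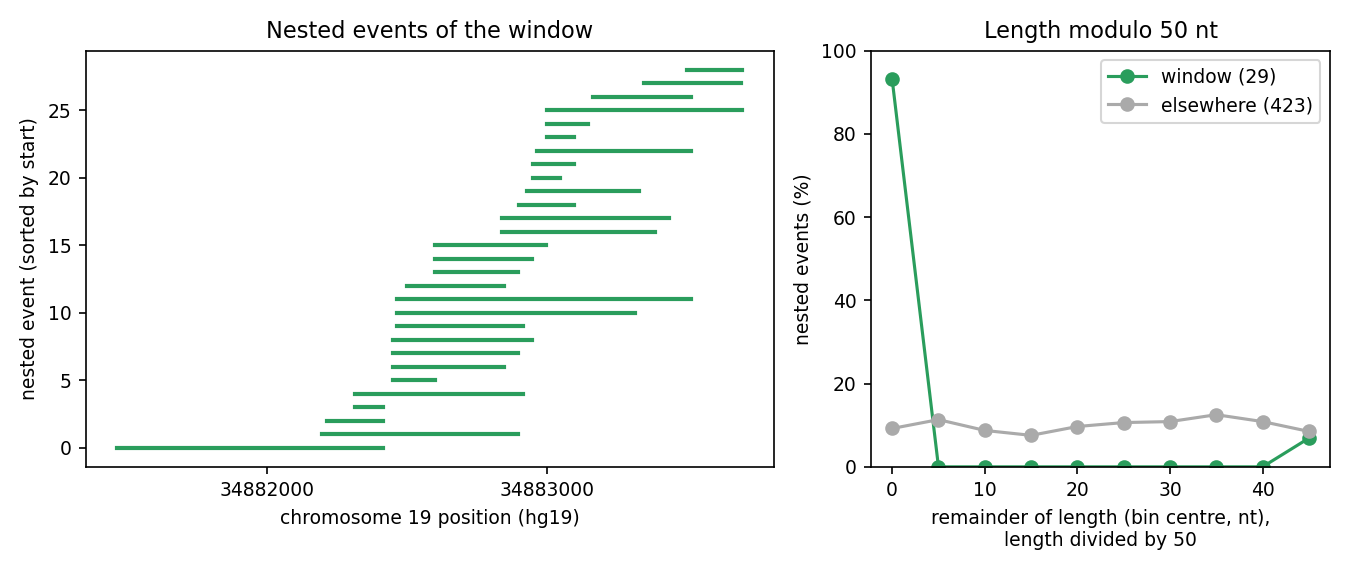
Left, the 29 nested events of the window on chromosome 19 as lines over their hg19 positions, sorted by start. Right, percent of nested events by the remainder of their length divided by 50 nt, in bins of 5 nt, for the window and for the 423 events elsewhere; 93.1% of the window's events lie in the bin around 0, against 9.22% elsewhere.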

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

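A signal lay in rows that the site comparisons do not use: features whose strand is given as both plus and minus. They hold 25300 reads over 755 known introns, 558 reads over 46 join5 events, 282 reads over 31 join3 events and 125 reads over 11 nested events. Their median reads were 13, 5.5, 6 and 7 in that order. One of them, a join5 event on chromosome 18 from 12699165 to 12699828 with 140 reads, is among the 10 with the most reads of its class. A nested event on chromosome 7 from 41733860 to 41734882 with 35 reads is as well. What the double strand stands for is not stated in the files, and no explanation was tested.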

How the results depend on the processing

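Alternatives on both-strand features, the chromosome 19 window, pairs, peaks, introns by reads, runs of rows, all events and pooled shares without the top 10 were chosen after the data were seen. No paired analysis was possible because the tables hold no value per library; leaving out replicates, replicate blocks, other normalizations and other time scales were not run for the same reason, and the set tests also lacked gene names. Over 15 results, 9 of 43 alternatives stayed within the counting interval (for counts, within 1.5 times) and 34 moved; the cause was not tested beyond what each setting removes. Against intron reads alone, join3 came to 1.06% and join5 to 1.25%. With features of at least 10 reads, join3, join5 and nested reads were 0.674%, 0.812% and 0.0582% of all, and the ratios join3 to join5, nested to join5 and nested to join3 were 0.830, 0.0717 and 0.0864. Without the 10 features with the most reads per table, the shares were 0.910%, 0.977% and 0.122%, and the first 2 ratios 0.931 and 0.124. Without the chromosome 19 window, nested reads were 0.122%, their ratios 0.100 to join5 and 0.118 to join3, and chromosome 19 held 5.91% of nested events; with at least 10 reads it held 21.1%. Within the first run of rows nested reads were 0.0960 per join5 read. The pooled join5 share there was 34.1%, within an interval that rests in part on the same events. The join3 table has no runs. The intron length, weighted by reads in the report, was 390 nt unweighted over introns with at least 10 reads, and 336 nt weighted without the 10 introns with the most reads. The pooled share of the own intron depended most on the minimum: for join5 22.9% at 10 reads, 48.4% at 50, 12.1% over all events and 18.9% without the 10 events with the most reads; for join3 17.5%, 48.5%, 10.7% and 17.4%. With events of at least 10 reads, the peak at 3 nt held 3.48% of join5 events (1.97% over all) and the peak at 4 nt 1.33% of join3 events (2.61% over all). Both values at 10 reads rest on few events and carry no interval. Of introns with at least 100 reads 10.5% held an event. With at least 10 reads on both events 78 introns kept an exon-sized pair, with a median log2 ratio of 0.021. The listing minimum of 4 reads bounds every statement on rare events.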

Other observations

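The tests in this part were chosen after the results were seen, except the rate of events per length of intron, whose prediction was written first.

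Chromosomes differed in the share of their listed introns that held a join event. It was lowest on chromosome X, where 44 of 1426 introns held one (3.09%, interval 2.31 to 4.12%), and highest on chromosome 21, where 36 of 446 did (8.07%). Chromosome 20 had 6.85% (5.57 to 8.39%). Rates per class of length and reads over the whole list gave 4.33% for X, 6.62% for 21 and 4.93% for 20, so that X and 20 differ from what their introns' lengths and reads give by more than the counting interval of the chromosome, and 21 does not. Chromosomes 8, 11 and 16 differed in the same sense, with 3.46%, 4.84% and 4.46% against 4.95%, 3.97% and 3.62%. The 23 chromosomes were compared without a correction for their number.

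The exon-length spacing of join5 and join3 sites has 2 candidate explanations that the tables can address. Chance placement is argued against, since it gave at most 104 exon-sized pairs in 1000 draws against 268. An exon that the intron list lacks, joined on both sides, stays open: with 20 or more reads together, 52.3% of pairs (43.7 to 60.8%), or 59.1% with 1 pair per intron (49.7 to 67.8%), were within 2-fold, against 69.1% of neighbouring known introns with as many. The second interval ends close to that value, and several pairs of 1 intron share events in the first. With 20 to 49 reads together, both intervals held the 68.9% of neighbouring introns. The values were 62.7% of 75 pairs (51.4 to 72.7%) and 66.2% of 68 with 1 pair per intron (54.3 to 76.3%). With 100 or more reads together, both values lay further below: 33.3% of 30 pairs (19.2 to 51.2%) and 43.5% of 23 with 1 pair per intron (25.6 to 63.2%), against 69.6%. Those pairs are few, and reads of 1 side can be split over several events, so the balance does not decide. Whether such an exon would stay in the mature RNA or be removed in a later step is open too, and the order in which parts of an intron are removed was not tested. No biological explanation from the design was tested, since the tables have no release times.

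The crowded window of chromosome 19 may come from reads aligned across a tandem repeat. That would put event lengths at multiples of 1 unit. The unit of 50 nt was itself taken from these lengths, so the 93.1% found at its multiples is not a test of it. A search over units gave 25 nt, whose multiples hold the same 27 events. With the best unit from 20 to 200 nt chosen again in each of 10000 draws, other nested events reached at most 58.6%, and the window's own sites moved at random at most 62.1%. The sequence was not examined, so the repeat stays a hypothesis, and splicing between like sites in repeat copies is open as well.

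Introns with a join event were longer than the rest, by 1070.5 to 410.0 nt at the median. More reads on these introns is argued against as the whole cause, since lists matched on reads reached a median of at most 426 nt. A constant chance per length of intron is argued against too: introns under 1 kb held 97.4 events per 1000 kb (91.8 to 103), introns of 1 to 10 kb 54.2 (51.5 to 57.1) and longer ones 19.6 (15.3 to 24.8). An effect of length that grows more slowly than length itself stays open. The lower read depth of long introns hides events under 4 reads, which could lower their rate but would not make introns with an event longer. From under 1 kb to 1 to 10 kb, the share of introns with an event rose from 3.00 to 9.31% over all reads. It rose from 1.69 to 5.96% at 4 to 19 reads, 3.59 to 12.8% at 20 to 99 and 7.25 to 23.8% at 100 or more. Rates per length were not computed by read class, so the part of depth in the falling rate is not settled.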
